A study of Homo sapiens with 18 samples.

How the data were processed

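Poly(A)-selected RNA was sequenced from 18 libraries of HCT-116, an established human colorectal carcinoma line grown in DMEM with fetal bovine serum. The libraries formed 6 groups of 3 in 2 tables. The first table held Actin KO cells with an empty construct, the same cells labelled as over-expressing wild-type actin (ACTB-WT), and the same cells labelled as over-expressing mutant actin (ACTB-mut, the H73A form per the series design). The second table held a SETD3 control (SETD3 CT) and 2 SETD3 knockout lines (KO1 and KO2). SETD3 is the enzyme that methylates the histidine of actin that the H73A form lacks. The cell line label read HCT-116 for 17 samples and HCT-117 for 1 sample, KO2 replicate 3, which was kept in its group. The labels did not state whether the 3 replicates of a group were separate cultures, so the p-values measure the spread between these samples.

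The deposited values were RSEM expected counts per gene, without normalisation. Per the labels, the authors trimmed reads with Trim Galore 0.4.5 and cutadapt 1.15 and quantified them with RSEM 1.2.28 and Bowtie2 (version not given) on GRCh38. The annotation release and the strand setting were not given in the sources used here. Each table had 60683 gene rows, of which 36029 in the ACTB table and 36107 in the SETD3 table had no count in any library. Of all values, 83.4% and 83.8% were whole numbers within 0.005. All columns were matched to a sample, and 66 symbols were shared by more than 1 row. Counts were rounded to whole numbers before testing. Gene coordinates, GC content and transcript length came from GENCODE release 29, which matched 58496 identifiers.

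Each table was fitted on its own with all 3 of its groups in edgeR 4.0.16 under R 4.3.3. Genes were filtered by filterByExpr, which left 13882 genes in the ACTB table and 13846 in the SETD3 table. Libraries were scaled by TMM, and groups were compared with robust quasi-likelihood F tests. All tests were two-sided unless stated. Adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, and a call is an adjusted p below 0.05. Fold changes are log2 values from these fits. Their standard error (SE) was derived as the absolute fold change divided by the square root of its F statistic. Levels are CPM (counts per 1e6 counts of a library) scaled by TMM, given as mean ± SD over 3 libraries. Where a group had no count for a gene, the fold was bounded by a floor of 3 counts over the group. Where a group had 1 to 3 counts, the ratio of counts is given with an exact 95% counting interval. These intervals and floors cover counting error alone.

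The comparisons numbered 7, 3 in the ACTB table and 4 in the SETD3 table, the last of which set KO2 against KO1. The genes named first in each comparison were picked by a rule fixed before the data were examined, as were the main comparisons, the gene lists and the alternatives unless stated. The rule took the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries. Chance gives such a separation in 10% of genes for 3 libraries against 3. For the average of both SETD3 knockout lines the rule asked for a call in both lines in the same direction. Genes named from outside the rule came from the fixed lists or are said to have been chosen after their values were seen.

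The 33 gene lists were tested with camera in limma 3.58.1, at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists covered actin isoforms other than ACTB, SRF-MRTF cytoskeletal targets, immediate early genes, YAP-TAZ targets, actin assembly factors, cytosolic and mitochondrial ribosomal proteins, translation factors, ribosome biogenesis factors, cytosolic tRNA synthetases, integrins, focal adhesion components, cell-cell junctions, surface adhesion molecules, extracellular matrix and the BAF chromatin remodelling complex. They also covered mitotic genes, p53 targets, interferon-stimulated genes, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, ATF4 targets, endoplasmic reticulum chaperones, cholesterol synthesis, Wnt targets with stem cell genes, intestinal differentiation and the mesenchymal side of epithelial-mesenchymal transition. The last 6 were fixed as checks. Fibroblast, blood and neural markers stood for other cell types and liver-kidney markers for another cell line. Mitochondrially encoded transcripts stood for RNA quality and replication-dependent histones for poly(A) selection. Calls on these lists were not separated from such differences between the samples. The tests were repeated with an estimated correlation. The fry test was run beside them. Its directional p asks whether a list's genes moved on balance in a common direction and its mixed p whether they changed in either direction, and neither compares a list with other genes. Counts of called members are given over all genes and adjusted over the list alone. For all 42 list calls the median, the mean and the test had the same sign. Of the 231 list medians, 27 included a gene at 0 in a group, and 0 of them moved by 0.01 or more with such genes at their bound.

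The procedure was tested on simulated data. The changed genes, 50 per fold, were drawn from genes with a mean of at least 5 CPM, so the rates do not cover rarer genes. A simulated ACTB-mut against ACTB-WT called 8%, 38%, 72% and 88% of genes changed 1.5-, 2-, 4- and 8-fold. It also called 10 of 12923 unchanged genes. A simulated KO1 against CT called 0%, 6%, 54% and 76%, and 2 of 12862 unchanged genes. Camera called a raised list of 30 genes in both simulated comparisons and left an unchanged list uncalled in both. The simulated genes were drawn independently, so this does not test camera on lists whose members vary together. Because 2 comparisons with the same control share its noise, 50 simulations of unchanged groups on shared controls were run. No gene changed in them, and each gene was drawn independently, without trends common to many genes of a library. With no gene changed few genes can be called, so their overlap does not measure how many real shared calls control noise produces.

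The alternatives were DESeq2 size factors, upper quartile scaling, total counts, the DESeq2 1.42.0 Wald test, limma-voom, non-robust dispersion, no low-count filter, at least 1 CPM in 3 libraries, fits of the compared groups alone, a replicate block, removal of ACTB, ACTG1 and SETD3, leaving out each library, a fold limit of 1 on the log2 scale, pooled knockout lines and an estimated list correlation. Offsets for GC content and length, and removal of SETD3 CT replicate 2 with KO2 replicate 1, were added after the data were seen. The closest libraries of a group differed by more than counting error (chi-square per degree of freedom of at least 14.6), which argues against 1 library sequenced again under another name. Repeat libraries from 1 culture or RNA sample would also exceed counting error, so these were not excluded. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.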

Results

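RNA levels of 60683 annotated gene rows were measured in 18 HCT-116 libraries, 3 for each of 6 groups. Total counts were 7512656, 8099698 and 8774607 in the Actin KO libraries, 5144386, 7601018 and 5726946 in ACTB-WT, and 11271910, 10018975 and 7919495 in ACTB-mut. They were 9966534, 4898827 and 8091464 in SETD3 CT, 6526017, 7899891 and 6835427 in SETD3 KO1, and 3389586, 10961333 and 11652967 in SETD3 KO2. Biological variation between replicates was estimated in edgeR as a coefficient of variation, which leaves out counting error. Its median was 15.2% in the ACTB table and 22.7% in the SETD3 table for genes above 100 CPM. It was 92.2% and 103% for genes at 1 to 5 CPM, so small differences in rare transcripts were not detectable with 3 libraries a group. Mitochondrial transcripts held 0.636% to 1.615% of counts in the ACTB table and 0.815% to 1.695% in the SETD3 table. Ribosomal protein genes held 20.9% to 25.5% across both tables.

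The actin genes and SETD3 were read first. ACTB (beta-actin, ENSG00000075624, GRCh38 chromosome 7, 5527147 to 5563784, minus strand) stood at 16.7, 24.9 and 15.0 CPM in Actin KO, against 662 to 1456 CPM in the 9 SETD3 libraries, which carry no engineered ACTB by their labels. The libraries labelled ACTB-WT had 31.0, 29.2 and 23.2 CPM and those labelled ACTB-mut had 47.1, 32 and 43.0 CPM. Because ACTB RNA stayed near the knockout level in both, these groups are named here by their labels. ACTB differed from Actin KO by 0.56 (SE 0.28, adjusted p = 0.496) in ACTB-WT and by 1.11 (SE 0.28, adjusted p = 0.093) in ACTB-mut, and by 0.55 between them (adjusted p = 0.463). ACTG1 (gamma-actin, chromosome 17, 81509971 to 81523847), the other cytoplasmic actin, stood at 7360 ± 403 CPM in Actin KO, 8080 ± 452 in ACTB-WT and 6450 ± 617 in ACTB-mut (n = 3 each). Its difference between ACTB-mut and ACTB-WT was -0.32 (adjusted p = 0.0826; 0.003 adjusted over the list alone). ACTG1 stood at 3150 ± 603 CPM in SETD3 CT, 3970 ± 344 in KO1 and 3000 ± 986 in KO2, and neither line passed the test.

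SETD3 (actin histidine methyltransferase, ENSG00000183576, chromosome 14, 99397746 to 99480889, minus strand) stood at 15.5, 14.0 and 36.0 CPM in SETD3 CT, at 6.81, 6.34 and 17.1 in KO1 and at 15.6, 22.3 and 27.7 in KO2. The differences from CT were -1.12 (SE 0.52, adjusted p = 0.879) in KO1 and 0.01 (SE 0.51, adjusted p = 1) in KO2, so a lower SETD3 RNA level was not detectable in either line. These values are counts over the whole gene and do not show an edit of its sequence. In the ACTB table SETD3 stood at 18.3, 17.4 and 13.5 CPM in Actin KO, 9.74, 27.7 and 24.9 in ACTB-WT, and 29.9, 32.7 and 33.0 in ACTB-mut, with a difference of 0.96 (adjusted p = 0.278) between ACTB-mut and Actin KO. SMARCA4 (the BRG1 ATPase of the BAF complex, chromosome 19, 10960825 to 11079426), named in the series title, stood at 182 ± 22.3 CPM in Actin KO, 208 ± 24.8 in ACTB-WT and 156 ± 28.9 in ACTB-mut, and at 189 ± 53.6, 215 ± 12.4 and 183 ± 37.0 CPM in SETD3 CT, KO1 and KO2. None of its differences passed, the lowest adjusted p being 0.287 for ACTB-mut against ACTB-WT.

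**Figure D1:**
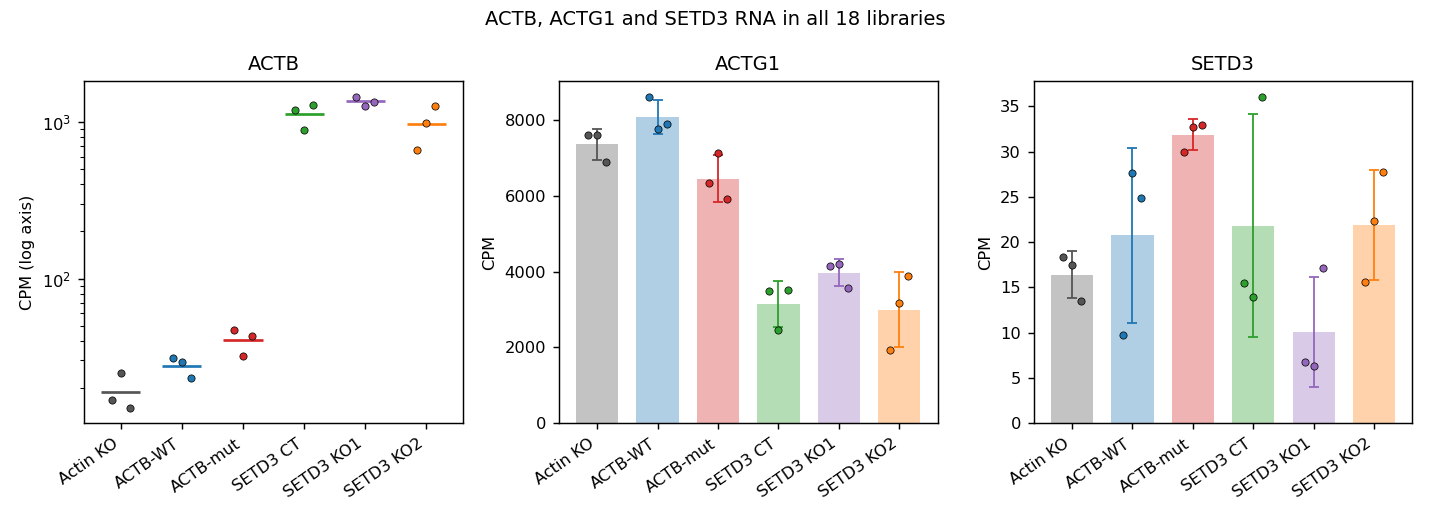
CPM of ACTB (log axis, lines at the mean), ACTG1 and SETD3 (bars are means, error bars SD) in the 6 groups, with a point for each of the 18 libraries. ACTB stays below 50 CPM in all 9 libraries of the ACTB table and at 662 or more in the SETD3 table.

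ACTB-WT against Actin KO compared the libraries labelled with wild-type actin with the knockout. LY6D, a surface protein of stratified epithelium (chromosome 8, 142784880 to 142786592), rose from 3.21 ± 0.313 to 172 ± 17.4 CPM (n = 3; log2 change 5.74, SE 0.25, adjusted p = 5.41e-09). The keratins KRT13 and KRT17 rose from 0.485 to 46.0 CPM (log2 change 6.51, adjusted p = 0.00391) and from 2.18 to 26.2 CPM (3.58, adjusted p = 0.0149). ANXA10, a gastric and intestinal annexin (chromosome 4, 168092515 to 168187690), rose from 1 count in the 3 knockout libraries to 17.3 ± 4.11 CPM, a ratio of 435 (77.5 to 17200; adjusted p = 4.94e-04). TAGLN, a smooth-muscle actin-binding protein (chromosome 11, 117199321 to 117204782), rose from 7.08 ± 6.15 to 144 ± 16.4 CPM (4.35, SE 0.56, adjusted p = 0.00172). BMP4, a secreted growth factor of the Wnt and stem cell list (chromosome 14, 53949736 to 53958761), rose from 169 ± 21 to 769 ± 39.4 CPM (2.19, SE 0.14, adjusted p = 3.82e-07). The glucose transporter SLC2A1 rose from 75.8 ± 14.7 to 437 ± 0.613 CPM (2.53, SE 0.18, adjusted p = 1.35e-06), and the Wnt antagonist DKK1 from 401 to 864 CPM (1.11, adjusted p = 9.73e-06).

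SPARC, a matrix-binding glycoprotein (chromosome 5, 151661096 to 151687165), fell from 202 ± 39.3 to 31.3 ± 9.82 CPM in ACTB-WT (log2 change -2.69, SE 0.21, adjusted p = 3.59e-06). VIM, the intermediate filament of mesenchymal cells (chromosome 10, 17228259 to 17237593), had 0 counts in all 3 ACTB-WT libraries against 5.74 ± 2.36 CPM, at least 35-fold lower (adjusted p = 0.0118). ITGA6, the laminin-binding integrin alpha chain (chromosome 2, 172427354 to 172506282), also had 0 counts against 6.24 ± 6.13 CPM, at least 37.2-fold lower (adjusted p = 0.0231). In the 9 SETD3 libraries VIM stood at 0 to 0.582 CPM and ITGA6 at 0 to 10.4 CPM. The caveolar coat gene CAV1 fell from 165 ± 13.8 to 45.3 ± 3.75 CPM (-1.86, adjusted p = 6.39e-06). The AP-1 subunit FOSL1 fell from 314 to 134 CPM (-1.22, adjusted p = 1.59e-04) and zyxin, ZYX, from 463 to 210 CPM (-1.14, adjusted p = 0.00754). The stem cell factor SOX9 fell from 32.1 to 11.3 CPM (-1.5, adjusted p = 0.00997).

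The other genes named by the rule in this comparison were the placental-type phosphatase ALPP (ratio 162, 44.3 to 1340; adjusted p = 0.0182), the ubiquitin protease USP34 (ratio 63.1, 21.2 to 310; adjusted p = 0.012) and the Golgi protein ACBD3 (3.50, adjusted p = 0.0421) among the rises. The falls were GNG11, a G protein subunit (-5.77, adjusted p = 0.00245), the antiviral gene OAS1 (-5.18, adjusted p = 0.0497), HOXB8 (-4.95, adjusted p = 0.0359), the lysophosphatidic acid receptor LPAR1 (-4.92, adjusted p = 0.022), PARP10 (-4.79, adjusted p = 0.0125) and HOXA3 (-4.66, adjusted p = 0.0437). In edgeR 155 genes passed, 61 higher and 94 lower, of which 106 changed at least 2-fold, and 1559 genes had an unadjusted p below 0.05. With any 1 library left out 79 to 106 genes passed, with 79 without Actin KO replicate 1. ANXA10, KRT13, LY6D, TAGLN, VIM and GNG11 passed in all 6 such fits. The other 10 genes taken by the rule were lost in at least 1, OAS1 in all 6. Genes named from outside the rule, such as BMP4, SLC2A1 and SPARC, were not followed there. ITGA6 was lost without Actin KO replicate 1 or 2 or any ACTB-WT library (adjusted p up to 0.0938), and KRT17 without Actin KO replicate 1 or 2 or ACTB-WT replicate 3 (up to 0.232). With limma-voom VIM (adjusted p = 0.219, from 2.34e-05 over the alternatives) and ITGA6 (0.365, from 1.12e-05) did not pass.

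Among the fixed lists, interferon-stimulated genes were lower as a set in ACTB-WT than in Actin KO (33 measured, median -0.86, camera adjusted p = 1.04e-19). None rose and 9 fell over all genes, 18 adjusted over the list alone. IFI6 (chromosome 1, 27666061 to 27672218), a mitochondrial antiviral protein, fell from 143 ± 22.9 to 21.3 ± 4.72 CPM (-2.75, adjusted p = 8.05e-05). ISG15, the ubiquitin-like modifier, fell from 2080 to 1150 CPM (-0.86, adjusted p = 8.85e-04), the immunoproteasome subunit PSMB9 from 40.2 to 4.36 CPM (-3.24, adjusted p = 0.00261) and OAS3 from 80.7 to 30.6 CPM (-1.40, adjusted p = 0.00391). Genes of the mesenchymal side of epithelial-mesenchymal transition were lower (12 measured, 2 fell, 4 adjusted over the list alone, median -0.63, adjusted p = 1.8e-05), with SPARC and VIM called and NT5E (-4.43, adjusted p = 0.0844) not. Leaving out Actin KO replicate 2 or ACTB-WT replicate 1, 2 or 3 gave medians of -0.41, -0.38, -0.35 and -0.2. Without Actin KO replicate 3 the median of this list was -0.01 with the list still called (adjusted p = 0.00399; 1.06e-06 to 0.0353 over the alternatives). These 2 list calls held with an estimated correlation (adjusted p = 0.00668 and 0.0353).

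Intestinal differentiation genes were higher in ACTB-WT (14 measured, 1 rose, 5 adjusted over the list alone, median 0.44, adjusted p = 0.00126). This call was lost with an estimated correlation (adjusted p = 0.0697). The median was 0.67 without Actin KO replicate 1. The 1 member called over all genes was ALPP, named above as the placental-type phosphatase. It was lost without Actin KO replicate 1, 2 or 3 or ACTB-WT replicate 1 (adjusted p up to 0.0889). KRT18 stood at 6070 against 4550 CPM (0.42, adjusted p = 0.108). Mitotic genes were lower (46 measured, 0 called, 4 adjusted over the list alone, median -0.17, adjusted p = 0.0425; adjusted p = 0.243 with an estimated correlation), with the kinase PLK1 at 124 against 187 CPM (-0.59, adjusted p = 0.053). That list was lost in 5 of the 6 fits that left out a library, all but the 1 without ACTB-WT replicate 3 (adjusted p up to 0.274, with a median of -0.1 without Actin KO replicate 3), and with GC offsets (adjusted p = 0.0651; 0.00989 to 0.274 over the alternatives). Single called members of lists that did not pass were PHGDH of the ATF4 list (0.64, adjusted p = 0.0182), EIF3B of the translation factors (0.79, adjusted p = 0.0231), PPAN and URB1 of the ribosome biogenesis list (0.81 and -1.08), the histones H4C3 (0.47) and H1-2 (1.34), and IER3 of the immediate early genes (-0.69, adjusted p = 0.00864).

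ACTB-mut against Actin KO compared the libraries labelled with the H73A form with the knockout. SPARC moved the other way from its change in ACTB-WT: it rose from 202 ± 39.3 to 655 ± 92.7 CPM (n = 3; 1.70, SE 0.19, adjusted p = 9.1e-04). APOC1, an apolipoprotein, rose from 0.815 ± 0.904 to 34.8 ± 4.79 CPM (5.42, SE 0.71, adjusted p = 0.00159). PDLIM5, a PDZ-LIM scaffold of actin fibres, rose from 39.9 ± 12.1 to 129 ± 8.30 CPM (1.69, SE 0.21, adjusted p = 0.00114), and the peroxidase PRDX1 from 80.7 to 214 CPM (1.41, adjusted p = 0.00333). HGS, an endosomal sorting protein, fell from 287 ± 36.3 to 58.1 ± 10.6 CPM (-2.31, SE 0.17, adjusted p = 6.59e-06), and the kinase ARAF from 31.7 to 3.79 CPM (-3.05, adjusted p = 0.00499). The laminin chain LAMA5 fell from 16.9 to 3.60 CPM (-2.23, adjusted p = 0.0222). Integrins ITGA3 and ITGB4 fell from 308 to 156 CPM (-0.98, adjusted p = 0.00529) and from 223 to 113 CPM (-0.97, adjusted p = 0.0121). The replication helicase subunit MCM7 fell from 1050 to 684 CPM (-0.62, adjusted p = 0.0042).

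Further genes taken by the rule in ACTB-mut against Actin KO were USP34 (ratio 43.9, 14.7 to 215; adjusted p = 0.0237), the nuclear envelope gene SUN1 (1.67, adjusted p = 0.0278), MT-CO1 (1.52, adjusted p = 0.0119), the acyltransferase AGPAT4 (-3.54, adjusted p = 0.031), IFI27 (-3.03, adjusted p = 4.66e-04), the kinesin light chain KLC2 (-2.88, adjusted p = 0.0401), ICA1 (-2.32, adjusted p = 0.0298) and IFI6 (-2.15, adjusted p = 0.00138). In edgeR 128 genes passed, 45 higher and 83 lower, 61 of them by at least 2-fold, with 1597 at an unadjusted p below 0.05. With GC and length offsets 108 passed, 46 higher and 62 lower, of which 76 were among the 128. KLC2 (-2.63, SE 0.61, adjusted p = 0.0691; 0.00828 to 0.169 over the alternatives) and LAMA5 (-1.93, SE 0.44, adjusted p = 0.0637; 2.06e-04 to 0.121) did not pass there, with folds that moved by less than their SE (0.63 and 0.44 without offsets). With 1 library left out 34 to 77 passed, with 34 without Actin KO replicate 3. APOC1, SPARC, PDLIM5, PRDX1, ARAF, IFI27, HGS and IFI6 passed in all 6 such fits, and the other 8 genes taken by the rule were lost in at least 1, SUN1 and KLC2 in all 6. MT-CO1 was lost without Actin KO replicate 2 or 3 (adjusted p up to 0.07).

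Interferon-stimulated genes were lower in ACTB-mut as well (33 measured, 0 rose, 5 fell, 9 adjusted over the list alone, median -0.45, adjusted p = 1.45e-12; 0.0216 with an estimated correlation). OAS3 fell by 1.59 on the log2 scale (adjusted p = 0.00264) and ISG15 from 2080 to 1330 CPM (-0.65, adjusted p = 0.0135). Cytosolic ribosomal protein genes were higher (86 measured, 7 rose and 0 fell, 16 and 1 adjusted over the list alone, median 0.22, adjusted p = 1.2e-06; adjusted p = 0.22 with an estimated correlation), among them RPL31 from 692 to 1400 CPM (1.02, adjusted p = 0.00865), RPS27 (1.34, adjusted p = 0.0119), RPL5 (0.52) and RPL27 (0.44). Mitochondrially encoded transcripts were higher (15 measured, 4 rose, 11 adjusted over the list alone, median 1.02, adjusted p = 1.34e-12; adjusted p = 0.186 with an estimated correlation), with MT-CYB (1.41, adjusted p = 0.00729), MT-ND5 (1.08) and MT-ND2 (1.08). Without ACTB-mut replicate 3 the median of the mitochondrial transcripts was 0.31. The mitochondrial list was fixed as a check of RNA quality. Without Actin KO replicate 3 the median of the ribosomal proteins was 0.13.

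Smaller shifts in ACTB-mut against Actin KO were a rise of mitochondrial ribosomal proteins (78 measured, median 0.14, adjusted p = 0.041) and nuclear-encoded oxidative phosphorylation genes (51 measured, median 0.14, adjusted p = 0.0196), with 0 members called and both calls lost with an estimated correlation (adjusted p = 0.186 each). Focal adhesion components fell (50 measured, 1 rose and 3 fell, 1 and 7 adjusted over the list alone, median -0.18, adjusted p = 0.0274; adjusted p = 0.186 with an estimated correlation), with FLNA from 767 to 420 CPM (-0.87, adjusted p = 0.0122), ZYX (-1.16) and CAV1 (-0.75). Hypoxia and glycolysis genes fell (38 measured, 0 called, 4 adjusted over the list alone, median -0.25, adjusted p = 0.00658; adjusted p = 0.186 with an estimated correlation), with ENO1 at 3870 against 4920 CPM (-0.35, adjusted p = 0.0986). The fold changes of ACTB-mut against Actin KO correlated across genes with GC content (r = -0.34 over the 3828 genes above 32 CPM, which are not independent replicates). With GC offsets cytosolic ribosomal proteins stood at a median of 0.10 (adjusted p = 0.0437) and mitochondrial transcripts at 0.73. With those offsets the focal adhesion (-0.03, adjusted p = 0.451), mitochondrial ribosome (0.09, adjusted p = 0.766) and oxidative phosphorylation calls (-0.01, adjusted p = 0.867, the opposite sign) were lost. Over the alternatives these 3 lists ranged from 0.00521 to 0.451, 0.013 to 0.766 and 0.00368 to 0.867. Focal adhesion was also lost without Actin KO replicate 2 or 3 or ACTB-mut replicate 2 (up to 0.102, with medians of -0.11 without Actin KO replicate 3 and -0.05 without ACTB-mut replicate 2), oxidative phosphorylation without Actin KO replicate 2 or 3 or ACTB-mut replicate 1 (up to 0.0862), and the mitochondrial ribosome without any library but Actin KO replicate 2 (up to 0.153).

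ACTB-mut against ACTB-WT compared the libraries labelled with the H73A form with those labelled with wild-type actin. SPARC stood at 655 ± 92.7 against 31.3 ± 9.82 CPM (n = 3; 4.39, SE 0.22, adjusted p = 1.99e-08). LY6D stood at 0.856 ± 0.309 against 172 ± 17.4 CPM (-7.59, SE 0.29, adjusted p = 5.43e-10), and KRT13 at 1.40 against 46.0 CPM (-4.95, adjusted p = 0.0131). KRT17 fell to a ratio of 0.00395 (8.12e-04 to 0.0116; adjusted p = 4.3e-04) and ANXA10 to 0.00192 (4.84e-05 to 0.0108; adjusted p = 6.27e-04). BMP4 stood at 253 ± 34.0 against 769 ± 39.4 CPM (-1.61, SE 0.13, adjusted p = 9.02e-06), SLC2A1 at 77.1 against 437 CPM (-2.50, SE 0.18, adjusted p = 1.99e-06) and DKK1 at 569 against 864 CPM (-0.60, adjusted p = 0.00534). VIM was at least 37.9-fold higher in ACTB-mut (6.47 ± 4.31 CPM against 0 counts, adjusted p = 0.0122) and ITGA6 at least 36.4-fold higher (6.45 ± 3.67 CPM against 0 counts, adjusted p = 0.0219). SOX9 stood at 32.4 against 11.3 CPM (1.51, adjusted p = 0.011).

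The other named genes of ACTB-mut against ACTB-WT were PEG10, an imprinted gene (ratio 122, 21.6 to 4830; adjusted p = 0.0238), LPAR1 (5.30, adjusted p = 0.0155), the cytidine deaminase APOBEC3G (4.94, adjusted p = 0.0435), PARP10 (4.49, adjusted p = 0.0194) and GNG11 (4.40, adjusted p = 0.0173) among the rises. The falls were the follistatin-like FSTL4 (-4.11, adjusted p = 0.0172), TAGLN, which stood at 19.7 ± 4.89 against 144 ± 16.4 CPM (-2.86, SE 0.51, adjusted p = 0.0177), the actin-elongating factor EVL (-2.58, adjusted p = 0.00374) and ARAF (-2.54, adjusted p = 0.0123). In edgeR 172 genes passed, 88 higher and 84 lower, 95 of them by at least 2-fold, with 1666 at an unadjusted p below 0.05. With GC and length offsets 129 passed, of which 113 were among the 172. With 1 library left out 60 to 129 passed, with 60 without ACTB-WT replicate 2. SPARC, ANXA10, KRT17, LY6D and EVL passed in all 6 such fits, and the other 11 genes taken by the rule were lost in at least 1. Genes named from outside the rule, such as BMP4 and SLC2A1, were not followed in these fits. TAGLN was lost in all 6 (adjusted p from 0.0505 to 0.114). VIM was lost without ACTB-WT replicate 2 (adjusted p = 0.0525) and with limma-voom (0.18, from 1.33e-05 over the alternatives). ITGA6 was lost without ACTB-WT replicate 1, 2 or 3 or ACTB-mut replicate 3 (up to 0.0842). With limma-voom ITGA6 was lost as well (0.232, from 9.45e-06 over the alternatives).

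**Figure D2:**
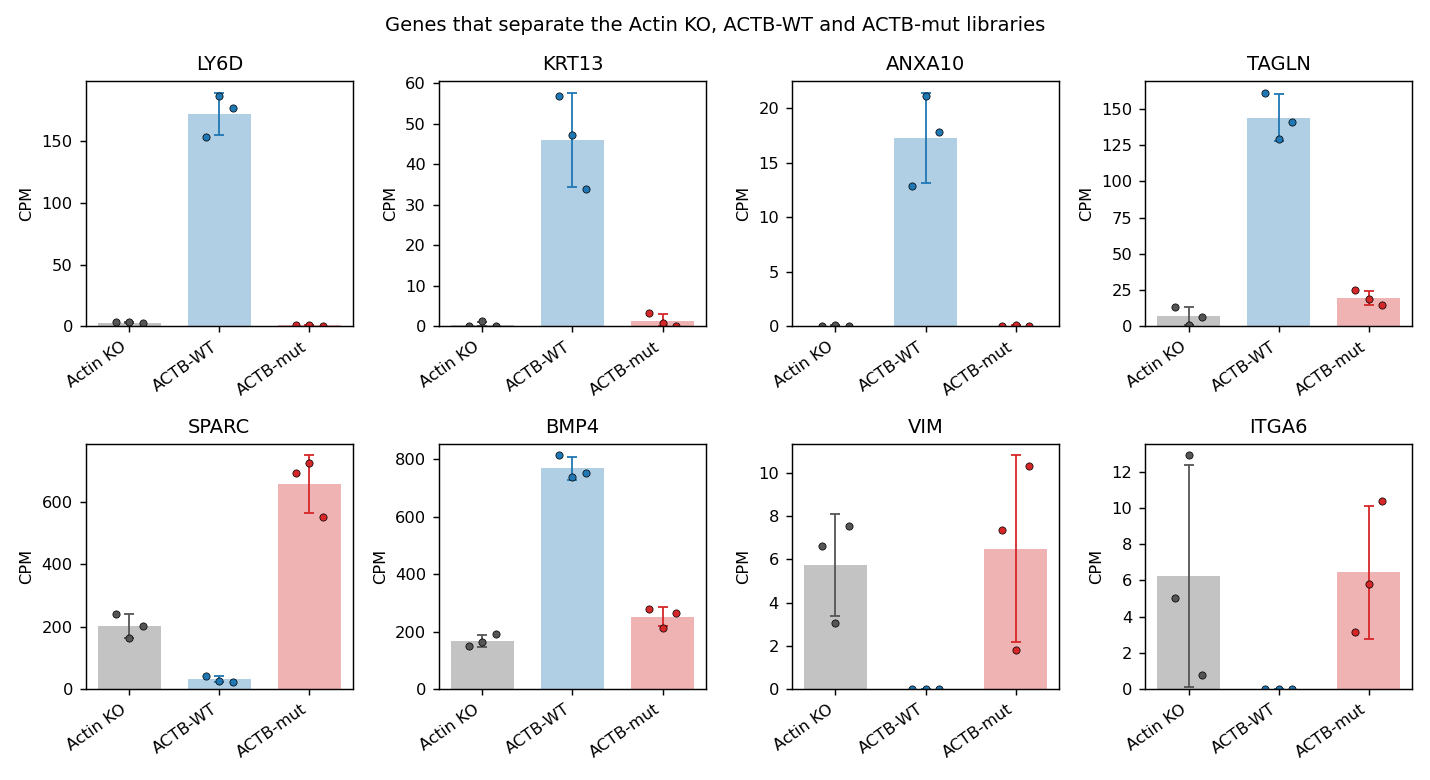
CPM of 8 genes in the Actin KO, ACTB-WT and ACTB-mut libraries, where bars are means of 3 libraries, error bars SD and points single libraries. LY6D, KRT13, ANXA10, TAGLN and BMP4 stand highest in ACTB-WT, SPARC stands highest in ACTB-mut, and VIM and ITGA6 have no counts in the 3 ACTB-WT libraries.

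Mesenchymal genes were higher as a set in ACTB-mut than in ACTB-WT (12 measured, 3 rose, 4 adjusted over the list alone, median 0.54, adjusted p = 3.97e-08). The call held with an estimated correlation (adjusted p = 0.0248). SPARC, VIM and S100A4 (0.69, adjusted p = 0.0424) were the called members. SRF-MRTF cytoskeletal targets were lower (30 measured, 4 fell, 7 adjusted over the list alone, median -0.19, adjusted p = 7.22e-04; adjusted p = 0.0587 with an estimated correlation). Among them the myosin heavy chain MYH9 fell from 274 to 162 CPM (-0.76, adjusted p = 0.0108), the light chain MYL9 from 207 to 125 CPM (-0.73, adjusted p = 0.0273) and the crosslinker FLNA from 688 to 420 CPM (-0.71, adjusted p = 0.0309). The list median was -0.08 without ACTB-WT replicate 2 and -0.31 without ACTB-mut replicate 1. Intestinal differentiation genes were lower (14 measured, 0 called, 4 adjusted over the list alone, median -0.63, adjusted p = 6.83e-04; adjusted p = 0.0587 with an estimated correlation), with the factor KLF5 at 13.5 against 49.9 CPM (-1.89, adjusted p = 0.0758). The list median was -0.33 without ACTB-WT replicate 1 and -0.41 without ACTB-mut replicate 3. Hypoxia and glycolysis genes were lower (38 measured, 2 fell, median -0.14, adjusted p = 0.00141). With an estimated correlation this call was lost (adjusted p = 0.141). The 2 called members were SLC2A1 and DDIT4 (-0.74, adjusted p = 0.0314). Without ACTB-WT replicate 2 the median of the hypoxia list was -0.22, and without ACTB-mut replicate 3 it was -0.24.

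Mitochondrially encoded transcripts were higher in ACTB-mut than in ACTB-WT (15 measured, 4 rose, 12 adjusted over the list alone, median 1.18, adjusted p = 2.28e-13; adjusted p = 0.233 with an estimated correlation), with MT-CO1 from 291 to 980 CPM (1.75, adjusted p = 0.00402) and MT-CO3 (0.69, adjusted p = 0.0171). The median was 0.49 without ACTB-mut replicate 3, the library with the highest mitochondrial share (1.615%). Cytosolic ribosomal proteins were higher (86 measured, 2 rose, 6 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.00463). With an estimated correlation this call was lost (adjusted p = 0.563). The 2 called members were RPL31 (0.84, adjusted p = 0.0211) and RPL27 (0.44). With GC offsets that median was 0.02 and the call was lost (adjusted p = 0.662, from 4.19e-04 over the alternatives), where the fold changes correlated across genes with GC content at r = -0.265. The fibroblast marker list was higher (7 measured, 2 rose, median 0.25, adjusted p = 0.0366). It was lost with an estimated correlation (adjusted p = 0.233), and VIM and S100A4 were its called members. The list was also lost without ACTB-WT replicate 1 or ACTB-mut replicate 1 or 3 (up to 0.152). Its median was 0.54 without ACTB-WT replicate 2 and 0.64 without ACTB-WT replicate 3. Interferon-stimulated genes did not pass in ACTB-mut against ACTB-WT (median 0.30, adjusted p = 0.0703), with IFI27 lower (-1.36, adjusted p = 0.0466) and PARP9 at least 26.3-fold higher (adjusted p = 0.023).

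Changes shared by ACTB-WT and ACTB-mut against the same Actin KO libraries were counted next. Both groups had 14 genes called higher, among them DKK1, MDK, USP34, ODC1, BMP4, PDLIM5, SUN1, S100A2, H4C3, CFD and SNHG9, against 0.198 from independent lists. Both had 17 genes called lower, among them CAV1, OAS3, IFI6, IFI27, ISG15, FOSL1, ZYX, VGF and ALDH1A3, against 0.562. KRT17 and LY6D rose in ACTB-WT and fell in ACTB-mut, and SPARC did the reverse. Simulated unchanged groups on shared controls gave at most 0 shared rises and 1 shared fall in 50 runs. With no gene changed few can be called there, so the part of the Actin KO libraries in the real shared calls was not measured. The fold changes correlated at r = 0.495 across 13882 genes against 0.498 in the simulations, while their covariance was 0.564 against 0.305. The simulations lacked trends common to many genes of a library, so the covariances are not like for like. The 3 Actin KO libraries cannot be split between the 2 comparisons.

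Adhesion, translation and chromatin, the subjects named in the series title, were read through their lists in the 3 ACTB comparisons and both SETD3 lines. Integrins (15 measured, 13 in the SETD3 table) gave adjusted p = 0.354, 0.454 and 0.924 for ACTB-WT against Actin KO, ACTB-mut against Actin KO and ACTB-mut against ACTB-WT, and 0.375 and 0.903 for KO1 and KO2, with ITGA6, ITGA3 and ITGB4 called as above. Cell-cell junction genes (43 and 45 measured) gave 0.847, 0.751, 0.712, 0.518 and 0.961 with 0 members called, JUP being lower in ACTB-mut than in ACTB-WT adjusted over the list alone (-0.57, adjusted p = 0.0863 over all genes). Surface adhesion molecules (28 and 29 measured) gave 0.847, 0.536, 0.712, 0.928 and 0.949 with 0 members called. Matrix and basement membrane genes (33 and 35 measured) gave 0.354, 0.627, 0.728, 0.995 and 0.997, with SPARC, LAMA5, TIMP1 (-0.51 in ACTB-mut against Actin KO, adjusted p = 0.0486) and COL18A1 (-1.46 in ACTB-mut against ACTB-WT, adjusted p = 0.0484) called. Focal adhesion genes gave 0.114 in ACTB-WT against Actin KO, where PDLIM5 rose and CAV1, ZYX and TRIP6 (-0.59, adjusted p = 0.025) fell. They gave 0.712 in ACTB-mut against ACTB-WT, where CAV1 (1.11, adjusted p = 0.0021) and TNS4 (1.65, adjusted p = 0.0092) rose.

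Translation initiation and elongation factors (53 and 52 measured) gave adjusted p = 0.588, 0.591, 0.977, 0.719 and 0.928 in the same order. EEF1A1 stood at 3300 in ACTB-mut against 1410 CPM in ACTB-WT (1.23, adjusted p = 0.0138), EEF1B2 rose against Actin KO (0.63, adjusted p = 0.0153) and EIF3C fell against ACTB-WT (-0.50, adjusted p = 0.0338). Ribosome biogenesis factors (85 measured) gave 0.847, 0.605 and 0.42 in the ACTB comparisons, with PWP2 (-0.80, adjusted p = 0.0326) and RRP1B (-1.02, adjusted p = 0.0344) lower in ACTB-mut than in Actin KO. Cytosolic tRNA synthetases (22 measured) gave 0.847, 0.627, 0.815, 0.457 and 0.918. The BAF complex (27 and 25 measured) gave 0.354, 0.622, 0.102, 0.928 and 0.803 with 0 members called. Actin isoforms other than ACTB (2 measured, ACTG1 and ACTA2) gave 0.971, 0.664, 0.712, 0.256 and 0.803. Actin assembly factors (50 and 51 measured) gave 0.187, 0.0552, 0.712, 0.841 and 0.833, with the bundler FSCN1 at 246 in ACTB-mut against 441 CPM in ACTB-WT (-0.84, adjusted p = 0.00143) and the linker EZR at 1010 against 642 CPM (0.66, adjusted p = 0.0215).

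The lists left over in the ACTB table did not pass, in the same order of 3 comparisons. These were YAP-TAZ targets (17 measured; adjusted p = 0.425, 0.895 and 0.625), SRF-MRTF targets against Actin KO (0.281 and 0.0824), immediate early genes (0.684, 0.324 and 0.712), p53 targets (0.97, 0.627 and 0.712), ATF4 targets (0.281, 0.908 and 0.381), endoplasmic reticulum chaperones (0.0535, 0.124 and 0.712), cholesterol synthesis (0.97, 0.414 and 0.55) and Wnt targets (0.0772, 0.613 and 0.289). Among chaperones HSP90B1 rose in ACTB-mut against Actin KO (1.04, adjusted p = 0.0173). Blood markers (0.847, 0.627 and 0.616), neural markers (0.97, 0.628 and 0.712) and liver-kidney markers (0.386, 0.627 and 0.712) did not pass. Neither did histones (0.0579, 0.312 and 0.635). In 63 of the 189 list tests without a call, over all 7 comparisons, the camera direction and the median or mean had opposite signs.

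SETD3 KO1 against SETD3 CT compared the first line labelled as a SETD3 knockout with its control. The antiviral tether BST2 (chromosome 19, 17402939 to 17405648) fell from 33.0 ± 9.12 to 2.85 ± 1.18 CPM (n = 3; -3.53, SE 0.43, adjusted p = 0.0126). IFI6 fell from 162 ± 27.0 to 42.7 ± 4.32 CPM (-1.93, SE 0.21, adjusted p = 0.00731). These were the 2 genes that passed in edgeR, with 796 at an unadjusted p below 0.05, and every KO1 library stood below every CT library for both. BST2 was lost without CT replicate 3 or any KO1 library (adjusted p up to 0.0998) and IFI6 without CT replicate 3 or KO1 replicate 1 or 2 (up to 0.0674). ISG15 stood at 1460 against 3100 CPM (-1.08, adjusted p = 0.0792), BMP4 at 55.9 ± 9.89 against 170 ± 34.2 CPM (-1.61, adjusted p = 0.0545) and the peptidase DPP4 at 11.0 ± 6.81 against 0.212 ± 0.222 CPM (5.79, adjusted p = 0.0545), and none of them passed. In the DESeq2 Wald test 65 genes passed and with limma-voom BST2 did not (adjusted p = 0.138, from 1.07e-11 over the alternatives). Without CT replicate 3 or KO1 replicate 1 or 2 the count was 0, and without CT replicate 2 it was 4.

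Interferon-stimulated genes were lower as a set in KO1 (36 measured, 0 rose and 2 fell, 6 adjusted over the list alone, median -0.86, adjusted p = 7.46e-14; 0.00304 with an estimated correlation). The p53 targets were lower (26 measured, 0 called, 2 adjusted over the list alone, median -0.46, adjusted p = 1.61e-05; 0.0296 with an estimated correlation), with the secreted factor GDF15 at 184 against 348 CPM (-0.91, adjusted p = 0.199). Cytosolic ribosomal proteins (86 measured, 0 called, 3 adjusted over the list alone, median -0.21, adjusted p = 6.76e-08), mitochondrial transcripts (0 called, 6 adjusted over the list alone, median -0.87, adjusted p = 6.83e-11) and immediate early genes (20 measured, 0 called, median -0.50, adjusted p = 0.00467) were lower, with RPL32 at -0.92 and MT-CYB at -1.86. These 3 calls were lost with an estimated correlation (adjusted p = 0.123, 0.0629 and 0.181). The median of the mitochondrial transcripts, the RNA quality list, was -0.48 without CT replicate 2. Focal adhesion genes were higher (51 measured, 0 called, median 0.21, adjusted p = 0.0292; adjusted p = 0.123 with an estimated correlation) and oxidative phosphorylation genes lower (51 measured, 0 called, median -0.15, adjusted p = 0.0228; adjusted p = 0.207 with an estimated correlation). Focal adhesion was lost without CT replicate 1 or 3 or KO1 replicate 2 or 3 (adjusted p up to 0.211), and oxidative phosphorylation without CT replicate 3 or KO1 replicate 1 or 2 (up to 0.224). The median of the latter was -0.07 without CT replicate 3, -0.08 without KO1 replicate 2 and -0.23 without KO1 replicate 3.

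SETD3 KO2 against SETD3 CT compared the second line with the same control. DPP4 (chromosome 2, 161992241 to 162074542), a brush-border peptidase, rose from 0.212 ± 0.222 to 25.8 ± 4.75 CPM (n = 3; 7.02, SE 0.86, adjusted p = 0.00984). IFI27 (chromosome 14, 94104836 to 94116698) rose from 84.1 ± 29 to 618 ± 82.6 CPM (2.88, SE 0.25, adjusted p = 6.72e-04) and LY6D from 9.65 ± 4.52 to 105 ± 38.0 CPM (3.43, SE 0.45, adjusted p = 0.0125). The nuclear receptor NR2F1 (chromosome 5, 93583224 to 93594615) fell from 95.8 ± 16.4 to 16.4 ± 4.30 CPM (-2.53, SE 0.29, adjusted p = 0.00607) and BMP4 from 170 ± 34.2 to 46.3 ± 2.16 CPM (-1.88, SE 0.24, adjusted p = 0.0118). The acyltransferase GPAT2 fell from 69.2 to 11.6 CPM (-2.59, adjusted p = 0.0207), the sulfotransferase HS3ST1 from 170 to 52.4 CPM (-1.70, adjusted p = 0.019) and the metallothionein MT2A from 2270 to 1080 CPM (-1.07, adjusted p = 0.0249). These 8 genes passed in edgeR, 3 higher and 5 lower, with 686 at an unadjusted p below 0.05 and 90 in the DESeq2 Wald test. IFI27 and NR2F1 passed in all 6 fits that left out a library. BMP4 was lost without CT replicate 1 or 3 or KO2 replicate 2 or 3 (adjusted p up to 0.136), LY6D without CT replicate 2 or 3 or KO2 replicate 2 or 3 (up to 0.159) and DPP4 without CT replicate 1 (0.051), and DPP4 also with limma-voom (0.165, from 1.94e-11 over the alternatives). The count fell to 3 without CT replicate 3 or KO2 replicate 2 and to 4 without CT replicate 1 or KO2 replicate 3. It fell to 1 with only the groups compared in the fit, and also to 1 with a replicate block.

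**Figure D3:**
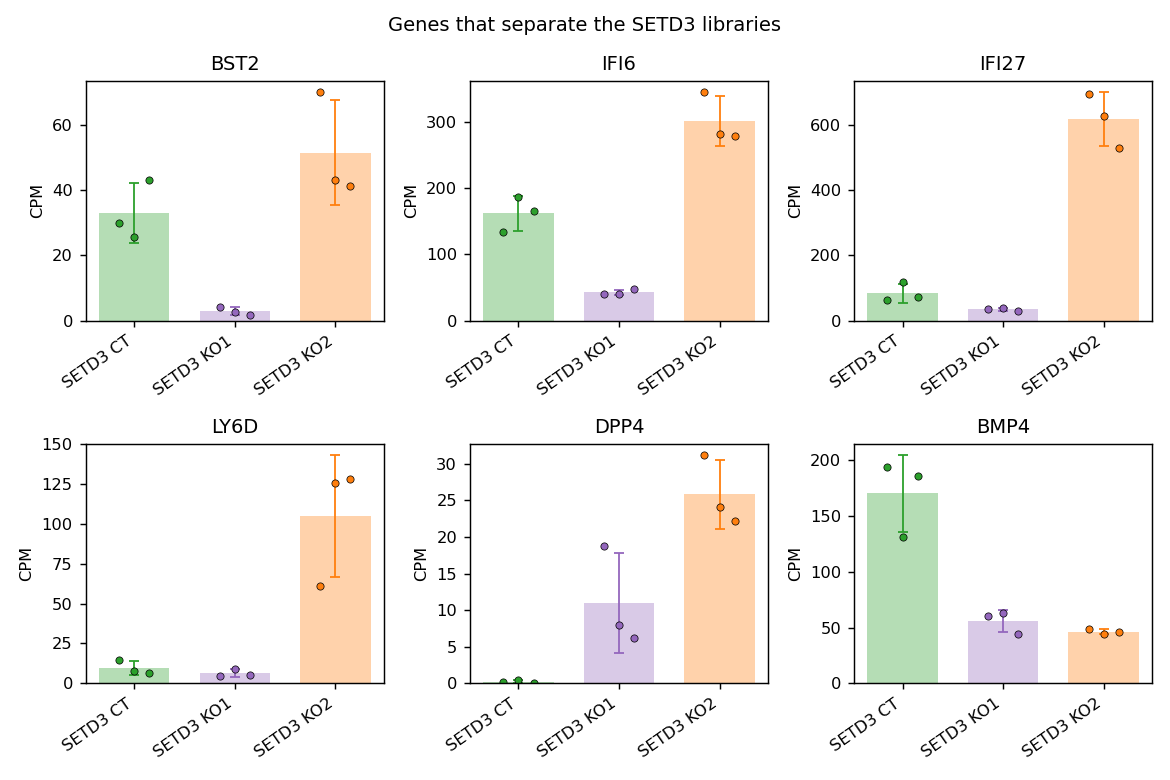
CPM of 6 genes in the SETD3 CT, KO1 and KO2 libraries, where bars are means of 3 libraries, error bars SD and points single libraries. BST2 and IFI6 stand lowest in KO1, IFI27 and LY6D stand highest in KO2, and BMP4 stands lower in both knockout lines.

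Among lists in KO2, ribosome biogenesis factors were higher (87 measured, 0 called, median 0.20, adjusted p = 0.00515; adjusted p = 0.257 with an estimated correlation), as were intestinal differentiation genes (12 measured, DPP4 called, median 0.43, adjusted p = 0.0462; adjusted p = 0.257 with an estimated correlation). Mitochondrial transcripts (0 called, 2 adjusted over the list alone, median -0.46, adjusted p = 0.00526), immediate early genes (0 called, 1 adjusted over the list alone, median -0.36, adjusted p = 0.0486) and p53 targets (0 called, median -0.32, adjusted p = 0.0486) were lower. With an estimated correlation these gave adjusted p = 0.334, 0.334 and 0.257. Without CT replicate 2 the ribosome biogenesis (adjusted p = 0.113) and mitochondrial transcript (0.362, median -0.12) calls were lost, and the p53 call was lost without any 1 library (0.0595 to 0.185). Immediate early genes were lost without any library but KO2 replicate 3 (up to 0.276; median -0.22 without CT replicate 2) and intestinal genes without CT replicate 1 or 3 or KO2 replicate 2 (up to 0.179). The intestinal median was 0.72 without CT replicate 3, 0.98 without KO2 replicate 1 and 0.24 without KO2 replicate 2. Interferon-stimulated genes stood at a median of 0.06 in KO2 (1 rose, adjusted p = 0.0969).

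The average of both knockout lines against CT was tested on the same fit. No gene passed in both lines in the same direction in edgeR, with 0.000722 shared falls from independent lists, while 27 did in the DESeq2 Wald test and 1 with limma-voom. For the average, 6 genes passed, with 787 at an unadjusted p below 0.05. The rule named none of them, and they are listed here after their values were seen: DPP4 rose (6.40, adjusted p = 0.0161), and BMP4 (-1.74, adjusted p = 0.0101), NR2F1 (-1.90, adjusted p = 0.0101), GPAT2 (-2.15, adjusted p = 0.0199), MT2A (-0.93, adjusted p = 0.0247) and HS3ST1 (-1.32, adjusted p = 0.0292) fell. Without CT replicate 1 or CT replicate 3, 0 genes passed for the average. The p53 targets (median -0.42, adjusted p = 3.55e-04), mitochondrial transcripts (-0.67, adjusted p = 2.64e-08), immediate early genes (-0.34, adjusted p = 0.0037), interferon-stimulated genes (-0.36, adjusted p = 0.00386) and cytosolic ribosomal proteins (-0.10, adjusted p = 0.0147) were lower and ribosome biogenesis factors higher (0.14, adjusted p = 0.0037). All 6 were lost with an estimated correlation (adjusted p = 0.104, 0.112, 0.194, 0.112, 0.439 and 0.194). Ribosomal proteins were lost without CT replicate 2, KO1 replicate 1 or 2 or KO2 replicate 3 (up to 0.175) and ribosome biogenesis without CT replicate 2 (0.0897). Its median was 0.22 without CT replicate 1 and 0.09 without KO1 replicate 3, that of the mitochondrial transcripts -0.3 without CT replicate 2, and that of the interferon list -0.22 without CT replicate 1. The fold changes of the lines correlated at r = 0.553 across 13846 genes, against 0.498 for simulated unchanged groups on shared controls. Their covariance was 0.633 against 0.417. Here too the simulations lacked trends common to many genes of a library, so the covariances are not like for like. The 3 CT libraries cannot be split between the lines.

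The 9 SETD3 libraries also differed along an axis other than their groups. CT replicate 2, KO1 replicate 3 and KO2 replicate 1 had positive scores on the first principal component (19.3, 5.44 and 34.2; 41.6% of the variance over 3776 genes above 32 CPM), and the other 6 libraries had negative ones. In the same 3 libraries the deviations from the gene means correlated positively with GC content across genes (r = 0.439, 0.269 and 0.463), and in the other 6 negatively (-0.48 to -0.0277). With GC and length offsets the counts of calls were 9 for KO1, 25 for KO2, 10 for the average and 17 for KO2 against KO1, among them all 2, 8, 6 and 4 genes called without offsets. Of the SETD3 list calls, 3 were lost: oxidative phosphorylation in KO1 (median -0.12, adjusted p = 0.0855; 0.00471 to 0.224 over the alternatives), and in KO2 intestinal genes (0.41, adjusted p = 0.084; 0.0273 to 0.257) and mitochondrial transcripts (-0.40, adjusted p = 0.0941; 2.02e-04 to 0.362).

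KO2 against KO1 tested whether the lines differed. IFI27 stood at 618 ± 82.6 in KO2 against 34.6 ± 3.62 CPM in KO1 (n = 3; 4.16, SE 0.27, adjusted p = 1.77e-05), IFI6 at 302 ± 37.3 against 42.7 ± 4.32 CPM (2.82, SE 0.21, adjusted p = 6.3e-05), BST2 at 51.5 ± 16.0 against 2.85 ± 1.18 CPM (4.17, SE 0.44, adjusted p = 0.00173) and LY6D at 105 ± 38.0 against 6.30 ± 2.54 CPM (4.05, SE 0.47, adjusted p = 0.00374). These 4 genes passed in edgeR, all higher in KO2, with 670 at an unadjusted p below 0.05. BST2, IFI27 and IFI6 passed in all 6 fits that left out a library, and LY6D was lost without KO1 replicate 1 or 3 (up to 0.0585). TAGLN stood at 87.6 against 15.4 CPM (2.51, adjusted p = 0.0676). Interferon-stimulated genes were higher as a set in KO2 (36 measured, 3 rose, 7 adjusted over the list alone, median 0.89, adjusted p = 9.6e-22; 8.31e-04 with an estimated correlation).

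Other lists that separated the lines were cytosolic ribosomal proteins (0 called, 9 higher adjusted over the list alone, median 0.19, adjusted p = 9.1e-09), with RPL37A at 4260 against 2350 CPM (0.86, adjusted p = 0.0935), hypoxia genes (0 called, 2 adjusted over the list alone, median 0.27, adjusted p = 0.00165), mitochondrial transcripts (median 0.36, adjusted p = 0.00396), mitotic genes (47 measured, median 0.22, adjusted p = 0.0361) and, lower, histones (8 measured, median -0.53, adjusted p = 0.0344). With an estimated correlation these gave adjusted p = 0.138, 0.0724, 0.301, 0.343 and 0.248. The mitotic call was lost without any library but KO2 replicate 1 (adjusted p up to 0.344), the histone call without any but KO2 replicate 2 (up to 0.302) and the mitochondrial call without KO1 replicate 2 (0.0513). The mitotic median was 0.13 without KO2 replicate 2 and 0.04 without KO2 replicate 3, and the histone median -0.12 without KO1 replicate 3. The histone list was fixed as a check of poly(A) selection and the mitochondrial list as one of RNA quality.

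**Figure D4:**
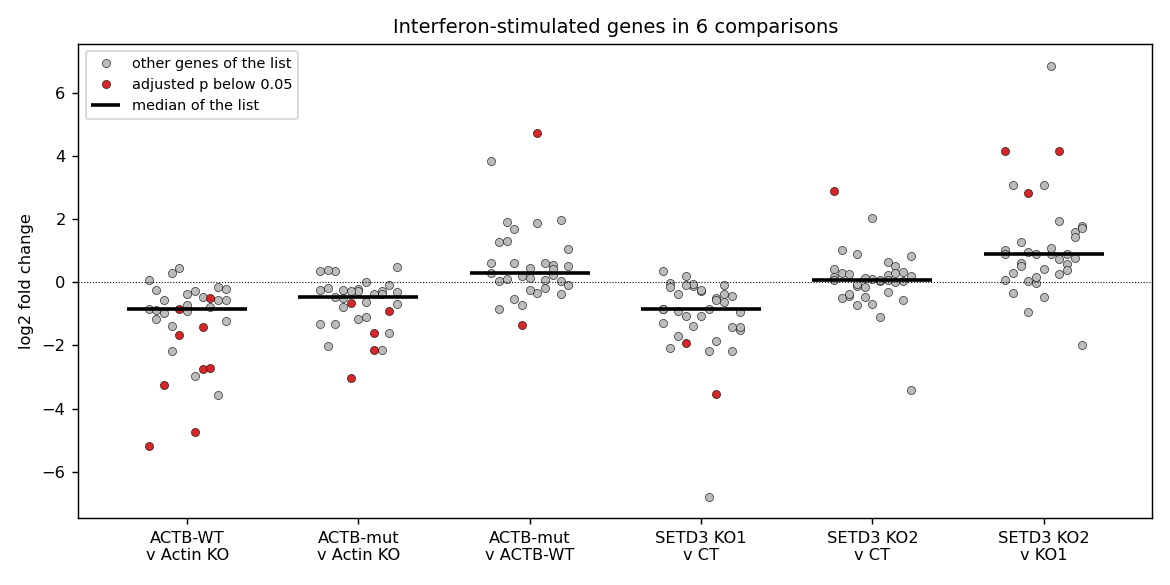
Log2 fold change of each measured interferon-stimulated gene (33 in the ACTB table, 36 in the SETD3 table) in 6 comparisons, with called genes in red, the list median as a black line, and genes without counts in a group drawn at their bound. The median lies at -0.86 and -0.45 for ACTB-WT and ACTB-mut against Actin KO, at -0.86 in KO1 and 0.06 in KO2 against CT, and at 0.89 for KO2 against KO1.

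The remaining lists did not pass in KO1 or KO2 against CT. They were SRF-MRTF targets (adjusted p = 0.995 and 0.833), YAP-TAZ targets (0.928 and 0.903), mitochondrial ribosomal proteins (0.258 and 0.359), ATF4 targets (0.822 and 0.359), chaperones (0.127 and 0.226), cholesterol synthesis (0.841 and 0.833), Wnt targets (0.995 and 0.619), fibroblast (0.233 and 0.833), blood (0.127 and 0.964), neural (0.0949 and 0.825), and liver-kidney markers (0.822 and 0.833). Mesenchymal genes (0.719 and 0.359) and histones (0.719 and 0.142) did not pass either.

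The last comparison set ACTB-mut against ACTB-WT beside the average of the lines labelled as SETD3 knockouts. Methylation of actin was not measured in these libraries. Across the 13028 genes tested in both tables the fold changes of ACTB-mut against ACTB-WT and of the SETD3 average correlated at r = -0.0543 and rho = -0.0546, with genes not independent replicates. BMP4 was the 1 gene called lower in both (0.0322 expected, one-sided Fisher exact p = 0.0318). MT2A and NR2F1 were called higher in ACTB-mut and lower in the SETD3 average (one-sided Fisher exact p = 4.06e-04). IFI27 and LY6D were called lower in ACTB-mut and higher in KO2 alone, not in the average (one-sided Fisher exact p = 4.11e-05). In KO1 against CT both had the sign of ACTB-mut and did not pass (IFI27 -1.28, LY6D -0.62). These Fisher p-values were not adjusted for the overlaps tested, rest on few genes and treat genes as independent. Of the 168 genes called in ACTB-mut against ACTB-WT and tested in the SETD3 table, 72 (42.9%) had the same sign in the SETD3 average.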

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

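The tests of ACTG1, of exchanged labels, of an effect common to both SETD3 lines and of the genes beside VIM were chosen after the results were seen. The sampling test of VIM and ITGA6 was also reworded after a first version, which asked only about read depth, had been run.

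The 2 SETD3 knockout lines differed from each other in a tested difference, KO2 against KO1, for 4 genes and 6 lists, of which 1 passed with an estimated correlation. IFI27 differed by 4.16 (-1.28 in KO1 and 2.88 in KO2 against CT), IFI6 by 2.82 (-1.93 and 0.90), BST2 by 4.17 (-3.53 and 0.64) and LY6D by 4.05 (-0.62 and 3.43). That list, the interferon-stimulated genes, differed by a median of 0.89 (adjusted p = 0.000831 with an estimated correlation), a test that measures the difference and says nothing of its cause. GC content and length trends are argued against by a median of 0.88 with offsets for them, and the 2 libraries with the fewest counts by a median of 1.04 without them. What differs between KO1 and KO2 beside their names was not in the labels, so a difference between clones, guides or cultures was not tested.

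VIM and ITGA6 had 0 counts in all 3 ACTB-WT libraries and means of about 6 CPM in Actin KO and ACTB-mut, while in the 9 SETD3 libraries VIM stood at 0 to 0.582 CPM and ITGA6 at 0 to 10.4 CPM, so a VIM level near 0 was not peculiar to ACTB-WT. Uneven sampling of few RNA molecules stays open, because 37 of the 83 other sets of 3 libraries (44.6%) also held at least 2 genes at 0 with 5 CPM in the remaining 6. Of these 37 sets, 27 held NME1-NME2, URGCP-MRPS24 or AC011558.1. No other set could hold VIM or ITGA6, since both had counts in every Actin KO and ACTB-mut library, so their absence there does not bear on sampling. The ACTB-WT set held 8 such genes against at most 4 in any other. The 8 include NME1-NME2 and also VIM and ITGA6, which prompted the test, so this count does not settle the question. A lost segment of 1 Mb on either side is argued against for ITGA6 by a median of 0.26 (SE 0.346) over 13 tested neighbours, and for VIM, whose median of 0.58 (SE 0.602) left it undecided, by 2 of 5 neighbours (RSU1 and HACD1) clearly above 5 CPM and 0 without counts in ACTB-WT, while a smaller loss was not tested. Another cell line behind the ACTB-WT libraries is argued against, since only 5 genes were off there and at 5 CPM in both other groups.

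ACTB RNA stayed near the knockout level in the libraries labelled ACTB-WT and ACTB-mut, at 23.2 to 47.1 CPM. By ACTB RNA an exchange of labels between Actin KO and ACTB-WT cannot be told apart from none, because the highest Actin KO library, at 24.9 CPM, lies above the lowest ACTB-WT library, at 23.2 CPM. Reads of an added ACTB assigned to ACTG1 cannot be told apart from their absence, because ACTG1 differed by 0.13 (SE 0.08) in ACTB-WT and -0.19 in ACTB-mut at a level far above ACTB. A construct whose sequence differs from the annotated gene was not tested, since reads were not used here.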

How the results depend on the processing

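GC and length offsets and the removal of SETD3 CT replicate 2 with KO2 replicate 1 were tests chosen after the results were seen. No result changed direction past its threshold under any alternative. Calls in the order ACTB-WT against Actin KO, ACTB-mut against Actin KO, ACTB-mut against ACTB-WT, KO1, KO2 and average against CT, and KO2 against KO1 were 155, 128, 172, 2, 8, 6 and 4. They were 358, 365, 446, 65, 90, 92 and 56 with the DESeq2 Wald test (27 shared by both knockout lines in the same direction, against 0) and 320, 371, 402, 58, 68, 85 and 58 with no low-count filter (16 shared). With total counts only KO1 had 5 calls and the average 10 (1 shared). With limma-voom ACTB-WT against Actin KO had 89 and KO2 against KO1 9 (1 shared). With GC and length offsets KO1 had 9, KO2 25, the average 10 and KO2 against KO1 17 (4 shared), and 147 of the 155, 76 of the 128 and 113 of the 172 ACTB calls stayed. With only the groups compared in the fit ACTB-mut against ACTB-WT had 104, KO1 1 and KO2 1, and with both lines pooled the average had 2. Without CT replicate 2 and KO2 replicate 1 together KO1 had 10 and KO2 against KO1 10 (3 shared). With any 1 library left out the counts ranged over 79 to 106, 34 to 77, 60 to 129, 0 to 4, 3 to 7, 0 to 7 and 3 to 5 (shared 0 to 2), where fewer libraries were tested. For the other settings the cause was not tested. The share of higher calls moved with them: KO1 from 0% to 43.08%, KO2 from 37.5% to 51.11%, the average from 16.67% to 64.13% and KO2 against KO1 from 100% to 66.07% with DESeq2, and to 44.44%, 64%, 50% and 70.59% with the offsets.

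A replicate block gave 89, 85, 83, 0, 1, 0 and 3 calls in the same order. No pairing by replicate number was seen across all comparisons. In ACTB-mut against Actin KO every ACTB-mut library correlated best with its own number (0.0928, 0.0393 and 0.0766), and in the other comparisons not every library did. The labels did not state whether equal numbers mark a pair, so a pairing was not excluded.

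The r of ACTB-mut against ACTB-WT with the SETD3 average ranged from -0.084 to -0.044 over the settings and from -0.082 to -0.016 without 1 library. Of the 42 list calls 34 stayed with GC and length offsets, 40 with limma-voom, 42 with the DESeq2 Wald test, 38 with no low-count filter, 39 with the replicate block and 7 with an estimated correlation. No scaling moved the median of all genes by over 0.1. Of simulated 4-fold changes in genes with a mean of at least 5 CPM, 72% were called in the ACTB table and 54% in the SETD3 table. The estimated biological variation within groups was higher in the SETD3 table (22.7% against 15.2% above 100 CPM). The effect of depth itself was not tested. Genes at 1 to 5 CPM numbered 4559 and 4462, with an estimated biological variation of 92.2% and 103%.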

Other observations

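The BMP target and squamous gene lists tested here were written after the main gene tables had been made, so these tests were chosen after those results were seen, as was a split of the SETD3 libraries with GC and length offsets.

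BMP target genes were read beside BMP4 in the ACTB table. Of 10 measured, 9 had positive fold changes in ACTB-WT against Actin KO with a median of 1.14, where ID2 (1.84, adjusted p = 0.0102) and ID1 (0.77, adjusted p = 0.00543) rose. In ACTB-mut against ACTB-WT the median was -0.68 (adjusted p = 0.00145 over the 3 comparisons), where ID2 (-1.77, adjusted p = 0.0138) and SMAD6 (-2.07, adjusted p = 0.0474) fell. The hypothesis was that lower BMP4 goes with lower BMP targets in ACTB-mut and in both SETD3 lines. It was not borne out: the highest adjusted p over the 3 comparisons was 0.973, with medians of 0.34 in KO1 and -0.06 in KO2.

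A wider squamous epithelial set beside KRT13, KRT17 and LY6D was the next hypothesis. In ACTB-WT against Actin KO it gave 0.286 in an unadjusted camera test, with a median of 0.25 over 13 measured genes and S100A2 (1.00, adjusted p = 0.0357) the only member called, so the hypothesis was not borne out. In KO2 against CT the same list stood at a median of 0.25 over 14 genes and gave 0.00442 in the unadjusted camera test, which was not part of the hypothesis.

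Splits of the libraries were counted for each set of calls. For ACTB-WT against Actin KO the real grouping was the only 1 of 10 splits with as many calls (155, highest other 0), as for ACTB-mut against Actin KO (128, highest other 1), ACTB-mut against ACTB-WT (172, highest other 0), KO1 (2, highest other 0), KO2 (8, highest other 0) and KO2 against KO1 (4, highest other 1). With 10 splits no share under 0.05 can be reached. With both lines pooled 5 of 84 splits gave at least the real 2 calls. They include the splits that set KO1 or KO2 apart (2 calls each), which are groups of the design and not random. The split that set CT replicate 2, KO1 replicate 3 and KO2 replicate 1 apart gave 198, which points to a structure of the samples other than their groups. These 3 libraries were the ones of the SETD3 table with positive first principal component scores (41.6% of the variance) and positive correlations with GC content across genes (0.439, 0.269 and 0.463, against -0.48 to -0.0277 in the other 6). With GC and length offsets the split gave 26 calls. The count thus fell with these trends taken out, and what gave rise to the trends was not in the labels. The other splits were not counted with offsets. For the correlation of ACTB-mut against ACTB-WT with the SETD3 knockouts, 29 of 84 splits were as far from 0 as the real -0.0538, with -0.113 the furthest of the others, so grouping by chance stays open.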
